A study of Mus musculus with 20 samples.

How the data were processed

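RNA of cultured mouse CGNs was measured on 20 Affymetrix arrays. Of these, 12 carry 6 cultures, each on 2 array types (3 at 1.5 DIV and 3 at 6 DIV), and 8 carry 1 culture each on another array type (4 EnR control and 4 NFI-EnR, at 6 DIV). The deposited values are log2 probe set values. Per the submitters' processing notes they were made with RMA, whose version is not given in the sources used here, and compared with limma 2.15.1. The authors' deposited lists also give log2 fold changes, and a p-value and an adjusted p-value per probe set, with the method of adjustment not stated. Their temporal list holds 844 probe sets, 509 higher and 335 lower at 6 DIV, all at least 2-fold changed, with a largest adjusted p of 0.0994. Their NFI list holds 686, 294 higher and 392 lower, all at least 1.5-fold changed, with a largest adjusted p of 0.15. The lists share 212 probe sets. The labels call the replicates biological, from pooled litters. Each of the 3 array types has its own value table, normalised apart, so tests were run within a table. Array medians ran from 8.33 to 8.41 in the first temporal table and from 7.39 to 7.50 in the second. Arrays give no read depth, and their number limits the precision.

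Groups came from the sample titles. The value columns of the authors' lists were set against the value tables: the temporal list matched with a largest difference of 0, and the NFI list matched only with other arrays than its column names give. Both groupings of the NFI arrays are therefore reported, the sample records because they were fixed before the data were examined, and the authors' column names as an alternative chosen after the conflict was seen. Deviations of the paired arrays from their group means correlated at 0.348, 0.41, 0.489 and 0.42 under the sample records and at 0.714, 0.656, 0.476 and 0.682 under the authors' names. Each series follows its own replicate numbers, and the authors' 1 and 2 are 3 and 4 of the sample records. Replicate 2 of the sample records correlated best with number 1, and the authors' replicate 3 with number 4. The others correlated best with their own number. The pairing itself is stated in the design text.

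Tests were computed in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on the deposited log2 values, and figures in Python 3.11.15 with matplotlib 3.10.9. The temporal fit had no block, since the design text names no pairs there, and the NFI fit had the pair as a block. All p-values were two-sided. Those of limma were adjusted by Benjamini-Hochberg over 45037 probe sets, over both temporal tables together, and the threshold was an adjusted p of 0.05. The Fisher exact p of the gene lists, described below, was adjusted over the lists tested. In the overlap the camera p and the Fisher exact p were not adjusted. The 64 control probe sets were left out. The temporal tables share 100 further probe sets, tested once, whose changes correlated at 0.97 between the tables. A fold change is 2 to the power of the log2 difference.

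The plan was to test 1 probe set per gene, and every probe set if no table paired them with genes, which was the case. Names came from the authors' lists only, which cover 1317 probe sets, 1292 of them with 1 name and 25 with none or several, for 1283 genes. By gene number 1241 names were matched to a RefSeq table of mouse genes (GRCm38.p6), which was used for names only and changed 108. Other probe sets are unnamed here, among them 6 with larger rises and 3 with larger falls with time than the eighth named gene, and 12 and 7 with NFI-EnR. Chromosomes are those of the authors' tables, and no coordinates are given. Of 9 genes with several named probe sets, 0 were called in opposite directions.

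The named genes follow a rule set before the data were examined. It takes, per comparison, the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold whose replicates or pairs go 1 way, without unnamed clones, up to 4 members of each gene list with the smallest adjusted p, Gabra6, Grin2c, Wnt7a and 6 genes that have no name here (Nfia, Nfib, Nfic, Nfix, Cdh2 and Cntn2), and for the overlap the 8 genes per opposite direction with the largest smaller change. For the NFI comparison it was applied to the authors' names, because no probe set passed under the sample records, a choice made after the data were seen. A gene named under one comparison may be given its value in another, and some results that the rule takes are not reported here. The 20 gene lists, also set before, cover the cell cycle, granule progenitors and Hedgehog signalling, immature and mature granule neurons, the presynapse, receptors and the postsynaptic density, voltage-gated channels, axon guidance and adhesion, activity-induced genes, calcineurin and NFAT, the NFI family, cholesterol synthesis, the interferon response, p53 and cell stress, glycolysis and hypoxia, and markers of astrocytes, oligodendrocytes, microglia, endothelial cells and Purkinje cells or interneurons. The NFI family and the microglia and macrophage list had 0 named members. A set test against all genes was planned for these lists, and it could not be run without names for all probe sets, so a Fisher exact test of direction among called named genes took its place. The overlap used cameraPR with a preset correlation of 0.01, camera with an estimated correlation, and fry.

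The fits were tested on simulated data. With the spread of the temporal arrays, 15.7% of probe sets changed 1.5-fold, 61.9% of those changed 2-fold and 89.4% of those changed 4-fold were recovered. For the NFI fit the shares were 5.97%, 61.2% and 95.5% with the spread under the authors' names, and 2.99%, 41.8% and 80.3% with that under the sample records. Of 200 random sets, 0 had a camera p below 0.05. Probe sets were simulated without correlation between them, so this does not cover correlated sets such as those of the overlap. RNA quality was read from control probe sets at the 3' and 5' ends of Gapdh and actin. The lowest 3' minus 5' differences of the first temporal table were those of 6 DIV replicate 3, at -0.258 for Gapdh and 0.816 for actin. Without this replicate 2269 probe sets passed the temporal threshold. The highest were those of 6 DIV replicate 2, at 0.386 and 1.8 there and 0.723 and 1.51 in the second table, and no fit left out that culture alone. In the NFI arrays the Gapdh difference ran from 0.356 to 0.442 in pairs 1 and 2 of the sample records and from 0.444 to 0.949 in pairs 3 and 4.

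The alternatives were a filter on dim probe sets, quantile normalisation, median centring, an intensity trend in eBayes, a stricter threshold of 0.01, a minimum of 1.5-fold, the block added or removed, adjustment within each table, each replicate left out, pairs 1 and 2 or pairs 3 and 4 alone, and an estimated correlation. Chosen after seeing the data were the authors' naming with its own alternatives, an array batch block, and the temporal fit without 6 DIV replicate 3. The array batch block took the 2 sets of pairs as batches in place of the pairs, and the labels name no difference between these sets. The authors' list of shared probe sets was not used, since it repeats their other lists.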

Results

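Gene expression was measured with Affymetrix arrays in cultured cerebellar granule neurons (CGNs), the small excitatory neurons of the cerebellar cortex, grown from progenitors of CD1 mice at postnatal day 6. The first set of arrays followed the cultures over time, with 3 cultures sampled at 1.5 days in vitro (DIV) and 3 at 6 DIV. Each of these 6 cultures has an array of 2 types, which together hold 45037 probe sets. The second set, on 1 array type with the same probe sets, compared cultures that received a lentivirus for NFI-EnR when they were plated with cultures that received a lentivirus for EnR alone. All 8 were sampled at 6 DIV, as 4 pairs. NFI-EnR is labelled an NFI suppressor, and nuclear factor I (NFI) proteins are transcription factors. Values are log2 probe set values normalised by the authors, and the number of arrays, 20 in all, limits the precision of every comparison.

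The first comparison asks which genes change as CGNs mature in culture. Between 1.5 and 6 DIV, 19 of 22 named genes of mature granule neurons and all 13 of the presynapse rose. Over the same time 16 of 22 named genes of the cell cycle, 11 of 17 of immature granule neurons and 8 of 9 of cholesterol synthesis fell. Names exist only for probe sets on the authors' lists of changed probe sets, so these shares do not describe the full lists. Gabra6, whose GABA-A receptor subunit is typical of mature granule neurons, rose at least 41.0-fold, from 7.26 ± 0.40 to 12.62 ± 0.32 log2 units (SD, n = 3 cultures per group, limma adjusted p = 0.000199). Gabrb2 rose 13.3-fold, and both genes lie on chromosome 11 in the authors' deposited tables. Further large rises were those of Cbln3, a cerebellin of granule neurons, at least 28.2-fold, the neuronal pentraxin Nptx1 at least 23.5-fold, the cation channel gene Trpm3 at least 22-fold, Rnf112 at least 12.5-fold and the chloride transporter gene Slc12a5 13.6-fold. The transcription factor gene Ebf3 was at least 24.8-fold lower at 6 DIV (log2 change -4.63, SE 0.42, limma adjusted p = 0.00185). The netrin receptor gene Dcc was at least 21.3-fold lower, the basic helix-loop-helix factor gene Nhlh1 at least 12.6-fold, Frmd4b at least 10.2-fold, Igfbpl1 at least 9.67-fold, Rwdd3 at least 9.42-fold, Clic1 at least 9.25-fold and Tubb3, a neuronal beta-tubulin, 9.14-fold. For the 12 of these 15 genes given as at least, the lower mean was below the median of each array of its table, so dim signals may limit these folds and their order is not resolved. The array median served as the mark of a dim signal here and below, and no background level was measured. The words at least therefore mark a possible limit only, and for Clic1 the lower mean, 8.324, was barely below the lowest median, 8.326. By the same measure the changes with time of Rrm2, Racgap1, Ube2c, Cdc20, Cenpf, Top2a, Rassf4, Dab1, Dpysl3, Etv1, Unc13c, Grin3a, Plxna3, Slit3, Hk2, Grin2c and Neurod6 may be lower bounds on size.

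Of 22 named mature granule neuron genes, 19 rose and 0 fell, with Vsnl1 (log2 change 3.52) next to Gabra6, and with Grin2c, an NMDA receptor subunit of mature granule neurons (1.44), and Wnt7a (2.14) among them. All 13 named genes of the presynapse and vesicle release rose, among them the endocytic GTPase gene Dnm1 (2.65), Rph3a (2.61), Syt4 (2.03) and Unc13c (2.66). Of 16 voltage-gated ion channel genes 9 rose and 0 fell, including the sodium channel genes Scn2a (3.02) and Scn2b (2.23), the calcium channel gene Cacna1g (1.72) and Kcnab1 (1.48). Of 7 genes of glutamate and GABA receptors and the postsynaptic density, 5 rose and 0 fell, including Grm5 (1.74), Dlgap1 (1.33), Gabrb1 (1.32) and Grin3a (1.28). Of 22 cell cycle genes, 16 fell and 1 rose. Ube2c (-2.19), Cenpf (-1.83), Cdc20 (-1.76) and Racgap1 (-1.46) were among those that fell, and the one that rose was Ccnd1, cyclin D1 (1.56). Of 17 immature granule neuron genes, 11 fell, among them Sox11 (-2.23) and Nhlh2 (-1.78), and the one that rose was the Reelin adaptor gene Dab1 (2.35). Of 12 genes of granule progenitors and Hedgehog signalling 7 fell, including Rassf4 (-2.81), Barhl1 (-1.76) and Sufu (-1.27), and 2 rose, the Hedgehog co-receptor genes Cdon (1.65) and Boc (1.27). Of 9 cholesterol synthesis genes 8 fell and 0 rose, among them Fdft1 (-1.73), Fdps (-1.63) and Mvd (-1.52).

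The remaining groups were small or mixed. Of 24 axon guidance and adhesion genes, 11 rose and 4 fell, with Sema3a (2.13) and Plxna1 (2.12) higher and Plxna3 (-1.42) lower at 6 DIV. In the activity-induced group of 4 genes, Egr1 (2.72) and Nptx1 rose and Dusp1 (-1.16) fell. Of 5 glycolysis and hypoxia genes 4 rose, including Eno2 (3.37), while Hk2 fell (-2.03). The stress genes Hspa1b (2.06) and Txnip (2.00) rose, and Ccng1, the other named member of the p53 group, had a log2 change of 0.94 (limma adjusted p = 0.0519). In the calcineurin and NFAT group Ppp3ca (0.53) and Rcan2 (-0.20) were not past the threshold, nor were the interferon response genes Ifi35 (-0.83) and Ifitm3 (-0.85). Markers of other cells moved beside the neuronal groups. Of 16 astrocyte and Bergmann glia genes 3 rose, Apoe (2.53), Aldoc (1.95) and Acsl6 (1.23), and 1 fell, Vim (-1.44). Gfap, at 10.37 and 11.22 log2 units at 1.5 and 6 DIV, had a limma adjusted p of 0.515. Of 6 oligodendrocyte lineage genes Pdgfra (-1.66), Mbp (-1.58) and Bcas1 (-1.39) fell and Cspg5 rose (1.13). Of 9 genes of Purkinje cells, interneurons and unipolar brush cells, 4 rose, including Rora (1.90), and Eomes (-1.62) and Lhx1 (-1.40) fell. The endothelial, mural and fibroblast gene Sparc rose (1.77), and Fn1 had a log2 change of -0.11.

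**Figure D1:**
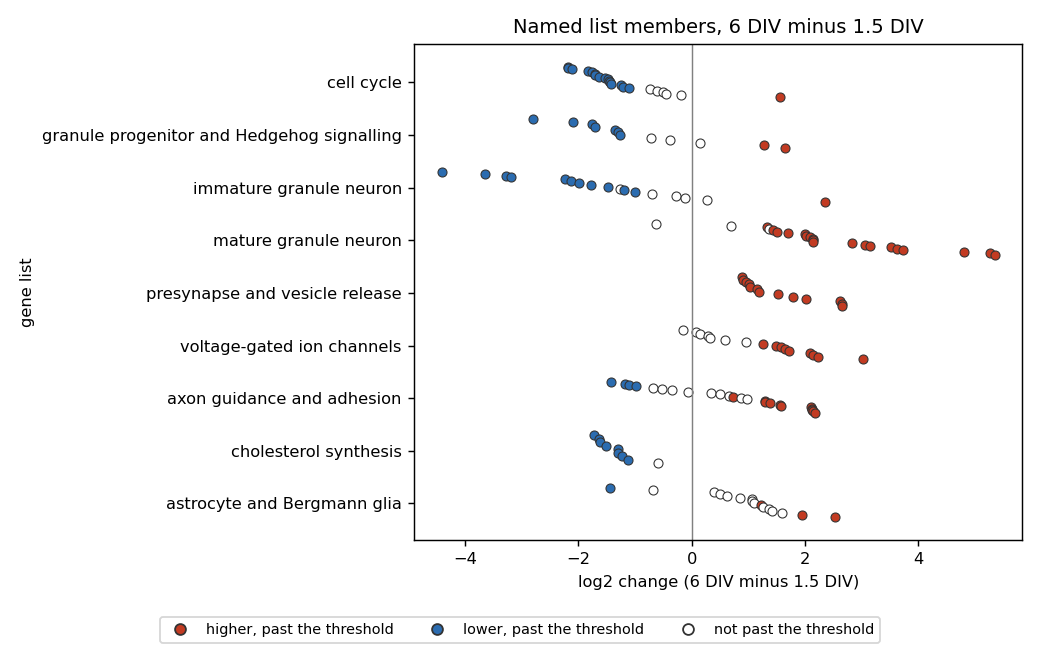
Log2 change between 1.5 and 6 DIV (x axis, 6 DIV minus 1.5 DIV) of the named members of 9 gene lists (y axis), 1 point per gene, filled red or blue where limma's adjusted p was below 0.05. The 13 presynaptic genes all lie right of 0, and the cholesterol synthesis genes all lie left of it.

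In all, 2772 of 45037 probe sets passed the threshold in limma, 1606 higher and 1166 lower at 6 DIV, and 7907 had an unadjusted p below 0.05. Genes of a list are not independent, so the list p-values below describe these genes only and not the spread between cultures. A Fisher exact test compared the directions of the called members of each list with those of the other called named genes. Its p, adjusted over 14 lists, was 3.3e-05 for the cell cycle, 0.000923 for mature and 0.001 for immature granule neuron genes, 0.00173 for cholesterol synthesis, 0.00693 for the presynapse and 0.0339 for ion channels. It was 0.0643 for progenitor and Hedgehog genes, 0.285 for receptors, 0.474 for the oligodendrocyte lineage, 0.598 for axon guidance, 0.832 for glycolysis, and 1 for the activity-induced, astrocyte and Purkinje groups. Without replicate 2 the presynapse and ion channels (Fisher exact p = 0.216 each) and cholesterol synthesis (p = 0.074) lost the call, as did the presynapse without replicate 1 (p = 0.0507), and ion channels without replicate 3 (p = 0.0542), without dim probe sets (p = 0.0757) and with the replicate as a block (p = 0.0613). Progenitor and Hedgehog genes passed without replicate 3 (Fisher exact p = 0.044). Adjusted over the list alone, the called members numbered 21 for the cell cycle, 11 for progenitors, 14 for immature and 21 for mature granule neuron genes, 13 for the presynapse, 5 for receptors, 12 for channels, 19 for guidance, 3 for activity, 1 for calcineurin, 9 for cholesterol, 2 for interferon, 3 for p53, 5 for glycolysis, 11 for astrocytes, 5 for oligodendrocytes, 1 for the endothelial group and 7 for the Purkinje group. Gene names came only from probe sets that the authors had selected on these samples, so neither count is independent evidence of a group's direction. Among members named only by the authors' NFI list, 3 of 3 presynaptic genes were called with time. None was called of the 5 cell cycle, 4 immature and 2 mature granule neuron genes named that way. Such members are by definition absent from the authors' temporal list. Of the 843 listed probe sets in the authors' temporal table that are not controls, 771 passed here, and all 843 had the same sign. Leaving out cultures lowered the number of calls, to 998 without replicate 1, 685 without replicate 2 and 1581 without replicate 3.

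The second comparison asks how expression at 6 DIV differs when NFI is suppressed. In the arrays that the authors' deposited table names NFI-EnR, 12 of 22 named genes of mature granule neurons were lower than in those it names EnR. Higher were 18 of 22 named genes of the cell cycle and 9 of 17 of immature granule neurons. Only probe sets on the authors' lists of changed probe sets carry names, so these shares do not describe the full lists of 38, 50 and 28 genes. Gabra6 was at least 58.9-fold lower, at 4.62 ± 0.69 log2 units against 10.50 ± 0.60 (SD, n = 4 cultures per group, limma adjusted p = 0.000196). Nptx1 was at least 22.9-fold, Prune2 at least 17.7-fold, the glial filament gene Gfap at least 14.7-fold, the oligodendrocyte lineage factor Olig1 at least 13.5-fold and Ramp1 at least 12.4-fold lower. The NFI-EnR means of these 6 genes lay below the median of each of the 8 arrays, so dim signals may limit these folds and their order is not resolved. By the same measure the NFI-EnR changes of Etv1, Tnc, Nrp1, Cdh8, Gas7, Hes5, Pdgfra, Mcm6, Id2, Ube2c, Racgap1 and Frmd4b, and the log2 changes of these 6, may be lower bounds on size. The glycolytic enzyme gene Aldoc was 18.3-fold lower. The protocadherin gene Pcdh17 was 7.41-fold higher, the ribonucleotide reductase gene Rrm2 6.23-fold, the potassium channel partner gene Kcnip4 5.14-fold, the cell adhesion gene Cxadr 4.10-fold, Lpar1 3.96-fold, S100a10 3.58-fold, Gask1b 3.45-fold and Cracd 3.44-fold.

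These directions rest on the column names of the authors' table, and the sample records name 4 of the 8 arrays otherwise. Each of its 8 columns held the values of 1 array of the deposited value table over 686 probe sets, with a largest difference of 8.9e-16, but under another name. The columns EnR 1 and 2 and NFI-EnR 1 and 2 matched arrays recorded as replicates 3 and 4 of the same groups. The columns EnR 3 and 4 matched the arrays recorded as NFI-EnR 1 and 2, and the columns NFI-EnR 3 and 4 those recorded as EnR control 1 and 2. The pairs were the same in both sources, and pairs 3 and 4 of the sample records had the same groups in both. In these undisputed pairs the log2 change of Gabra6 was -4.89 and -5.31, and over pairs 1 and 2 as recorded it was 6.66. The NFI genes were not named here, so that no gene tests either naming directly.

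**Figure D2:**
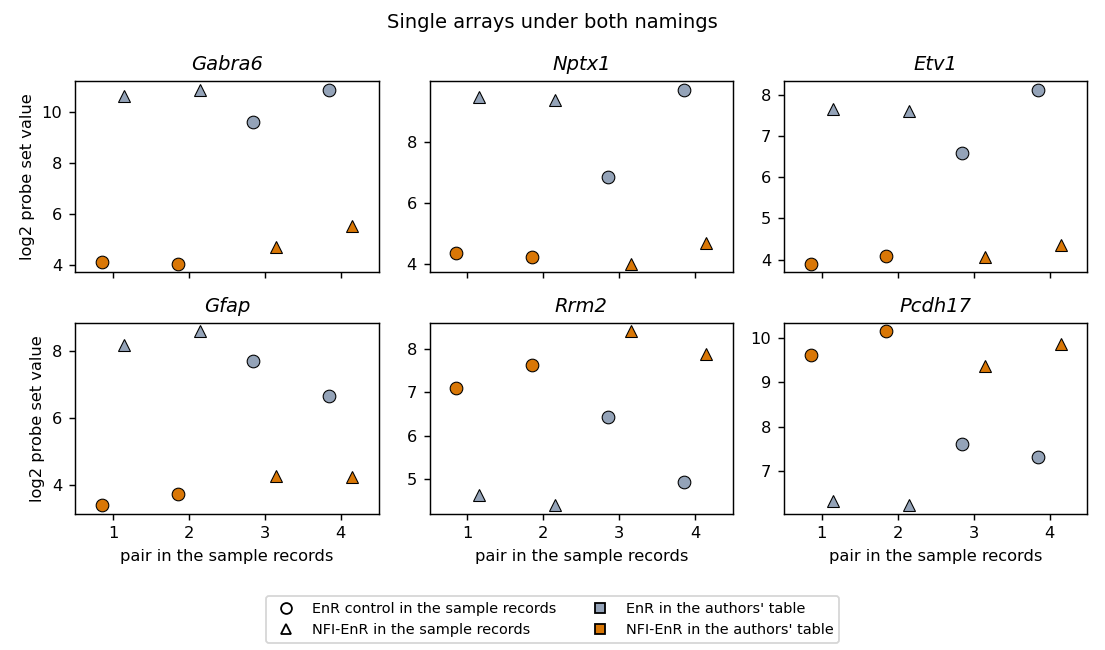
Log2 probe set value (y axis) of 6 genes in each of the 8 arrays by pair in the sample records (x axis), where circles and triangles give the group in the sample records and grey and orange the group in the authors' table. Arrays of pairs 1 and 2 have opposite groups in the 2 sources, and in pairs 3 and 4 the groups are the same.

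Grouped by the sample records, as planned before the data were examined, limma with the pair as a block called 0 of 45037 probe sets (smallest adjusted p = 0.781), and 2506 had an unadjusted p below 0.05. The named genes then had log2 changes from -0.97 to 1.02, and no member of any gene list passed. Grouped by the authors' column names, a choice made after the data were seen, 1348 probe sets passed, 530 higher and 818 lower, and 5869 had an unadjusted p below 0.05. The undisputed pairs 3 and 4 alone gave 1516 calls, 533 higher and 983 lower. Pairs 1 and 2 alone gave 2041, with 1225 higher and 816 lower by the authors' names, so that more were higher there and more were lower in pairs 3 and 4. The following values use the authors' names. Every list member called under them had the same sign in both undisputed pairs, but these pairs are part of that fit, so this is not independent evidence.

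Of 22 mature granule neuron genes 12 were lower and 0 higher, with Etv1 (-3.39), a transcription factor of mature granule neurons, Cbln3 (-2.82), the calretinin gene Calb2 (-2.32) and Wnt7a (-2.23) next to Gabra6. Grin2c had a log2 change of -0.35 (limma adjusted p = 0.345). Of 22 cell cycle genes 18 were higher, including Rrm2 (2.64), the replication helicase gene Mcm6 (1.41) and the topoisomerase gene Top2a (1.30), and Ccnd1 was lower (-1.85). Of 17 immature granule neuron genes 9 were higher and 0 lower, among them Sox4 (1.60), Dpysl3 (1.50), Dcx (1.27), which encodes a microtubule protein of migrating neurons, and the netrin receptor gene Unc5c (0.88). Genes of progenitors and Hedgehog signalling went both ways, with 2 of 12 higher, Id2 (1.27) and Barhl1 (0.94), and 4 lower, Mycn (-1.81), Boc (-1.57), Cdon (-1.19) and the Notch target Hes5 (-1.01). Of 13 presynaptic genes 5 were lower, including Unc13c (-2.09), Snap25 (-1.43), Syn2 (-1.08) and Syt1 (-0.88), and Cplx2 was higher (1.14). Of 7 receptor and postsynaptic genes 3 were lower, Homer2 (-1.58), Gabra2 (-0.88) and Dlgap1 (-0.61). Of 16 ion channel genes 6 were lower, including Kcnab1 (-1.58), Kcnh1 (-0.97) and Kcnn2 (-0.79), and 4 were higher, including Kcnip4 (2.36). Of 24 guidance and adhesion genes 9 were lower, among them the semaphorin receptor gene Nrp1 (-2.29), Slit3 (-1.84), Cdh10 (-1.83) and Cdh8 (-1.77), and 6 were higher, including Pcdh17 (2.89).

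Markers of glia moved beside these neuronal groups. Of 16 astrocyte and Bergmann glia genes 11 were lower, with Aldoc (-4.19), Gfap (-3.88), Apoe (-3.34), Tnc (-3.04) and Clu (-2.66) among them, and 2 were higher, the gap junction gene Gja1 (1.75) and the intermediate filament gene Vim (1.36). Of 6 oligodendrocyte lineage genes 3 were lower, with Olig1 (-3.76) and Pdgfra (-1.20) among them, and Mbp was higher (0.94). Of 9 Purkinje cell, interneuron and unipolar brush cell genes Eomes (1.49) was among 3 that were higher, and Aldoc and Rora (-0.68) were lower. In the endothelial, mural and fibroblast group Fn1 was higher (1.33) and Sparc lower (-1.11). The activity-induced genes Nptx1 (-4.52) and Egr1 (-2.71) were lower. In the calcineurin and NFAT group Rcan2 was higher (1.68) and Ppp3ca, a catalytic subunit of calcineurin, lower (-1.23). Of 9 cholesterol synthesis genes 2 were higher, with Hsd17b7 (0.88) among them, and 0 lower. Ifitm3 of the interferon group (1.07) and Ccng1 of the p53 group (0.59) were higher, and Eno1 of the glycolysis group (-0.84) was lower.

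**Figure D3:**
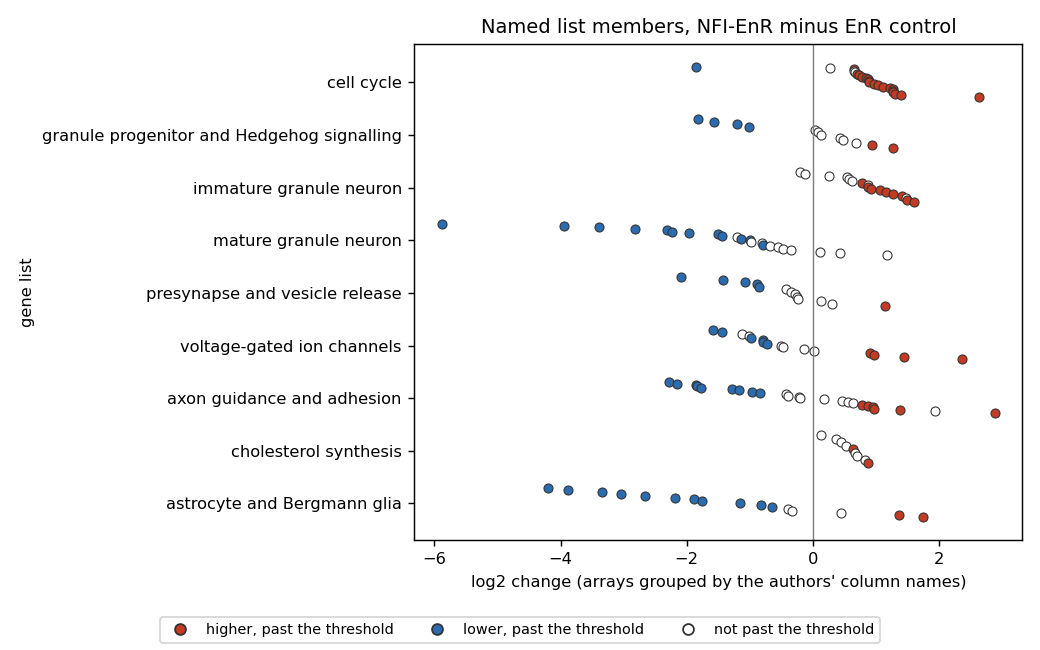
Log2 change between NFI-EnR and EnR control (x axis, arrays grouped by the authors' column names) of the named members of 9 gene lists (y axis), 1 point per gene, filled red or blue where limma's adjusted p was below 0.05. Of 22 cell cycle genes 18 are filled red, and all 12 filled mature granule neuron genes are blue.

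By the same Fisher exact test, with the same limit, p adjusted over 11 lists was 3.63e-06 for the cell cycle, 0.000996 for immature and 0.0167 for mature granule neuron genes. It was 0.252 for the astrocyte group, 0.631 for receptors, 0.65 for the presynapse and the Purkinje group, and 1 for progenitor, ion channel, guidance and oligodendrocyte genes. With the undisputed pairs alone the p of the first 3 lists was 1.92e-07, 0.00113 and 0.00399. The call of the mature granule neuron list was lost without pair 2 (Fisher exact p = 0.191), without pair 4 (p = 0.201) and without the block (p = 0.252), and that of the cell cycle without the block (p = 0.0895). Adjusted over the list alone, the called members numbered 21 for the cell cycle, 8 for progenitors, 14 for immature and 21 for mature granule neuron genes, 6 for the presynapse, 4 for receptors, 14 for channels, 20 for guidance, 3 for activity, 2 for calcineurin, 6 for cholesterol, 2 for interferon, 1 for p53, 3 for glycolysis, 14 for astrocytes, 5 for oligodendrocytes, 2 for the endothelial group and 8 for the Purkinje group. These names too come from probe sets the authors chose on these samples, which is not independent evidence. Among members named only by the authors' temporal list, 0 of 8 mature, 1 of 8 immature and 4 of 7 cell cycle genes were called. Such members are by definition absent from the authors' NFI list. Of the 686 probe sets in the authors' NFI table, 601 passed under its own names, and 0 passed under the sample records, where 184 had the sign the table gives. Without the pair as a block limma called 279 probe sets under the authors' names, and without pair 2 or pair 4 of the sample records it called 549 or 805.

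The third comparison asks whether genes that change with time also change when NFI is suppressed. By the authors' column names, 302 probe sets were higher at 6 DIV and lower with NFI-EnR, where independent lists would share 29.2. They included Gabra6, Nptx1, Cbln3 (log2 change 4.82 with time and -2.82 with NFI-EnR), Etv1 (3.06 and -3.39), Egr1 (2.72 and -2.71), Apoe (2.53 and -3.34) and Gas7 (2.57 and -2.38). A further 147 were lower at 6 DIV and higher with NFI-EnR, against 13.7 for independent lists. These included Cracd (-2.47 and 1.78), the neuronal factor Neurod6 (-2.67 and 1.75), Cd24a (-3.17 and 1.61), Ctxn1 (-2.26 and 1.61), Rrm2 (-1.54 and 2.64), Akap12 (-1.50 and 1.61), Dpysl3 (-1.99 and 1.50) and Eomes (-1.62 and 1.49). In the same direction, 18 were higher and 21 lower in both, against 18.9 and 21.2.

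**Figure D4:**
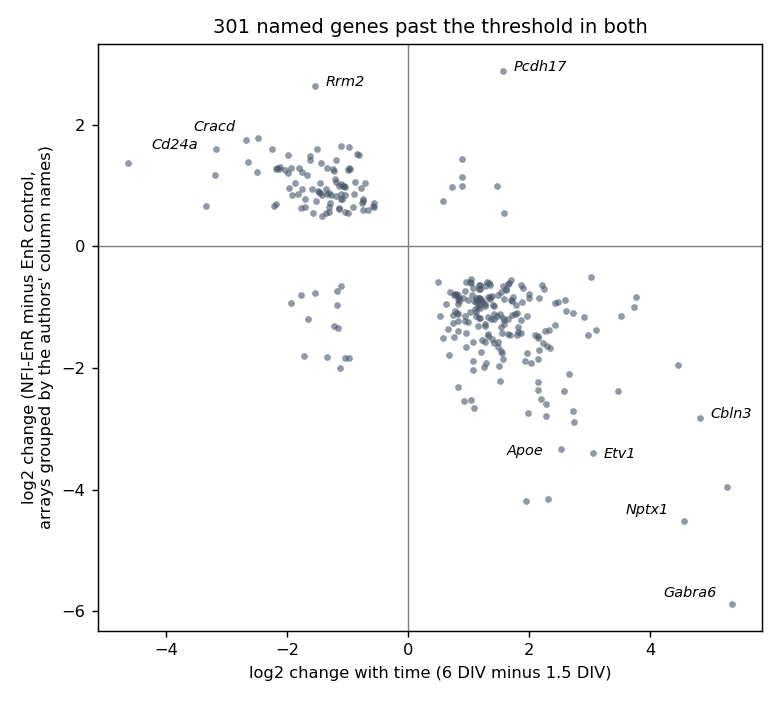
Log2 change with time (x axis, 6 DIV minus 1.5 DIV) against log2 change between NFI-EnR and EnR control (y axis, arrays grouped by the authors' column names) of the 301 named genes past the threshold in both comparisons, 1 point per gene. Of these, 187 lie at the lower right and 92 at the upper left.

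Of the 488 probe sets called in both, 92.0% had opposite signs (Fisher exact p = 2.3e-79, which describes these probe sets only, since genes are not independent). Across all 45037 probe sets the 2 log2 changes had a Pearson correlation of -0.349 and a Spearman correlation of -0.197. The 1606 probe sets higher at 6 DIV had a median NFI-EnR change of -0.17 (camera p = 3.95e-27 with a preset correlation, and p = 0.104 with an estimated correlation, fry p = 0.0389). It was -0.28 in pairs 3 and 4 of the sample records and -0.09 in pairs 1 and 2, and pair 1 alone went the other way, at 0.03 with 47.6% of these probe sets lower. The 1166 lower at 6 DIV had a median of 0.18 (camera p = 2.31e-16, and p = 0.0515 with an estimated correlation, fry p = 0.0196). It was 0.13 in pairs 3 and 4, 0.25 in pairs 1 and 2 and 0.29 without dim probe sets. The estimated correlation was 0.164 for the set higher and 0.0739 for the set lower at 6 DIV, and 0.193 and 0.19 under the sample records. All lie above the preset of 0.01, so the camera p with the preset correlation overstates the evidence for these sets. With the undisputed pairs 3 and 4 alone, 533 were called in both and 91.2% of them had opposite signs. Without a block in either fit 108 were called in both, and without pair 2 or pair 4 of the sample records 223 or 298. Grouped by the sample records, 0 were called in both by limma, the Pearson correlation was 0.0071 and the Spearman correlation -0.0142. The medians were then -0.093 for probe sets higher at 6 DIV (camera p = 5.56e-07, and p = 0.327 with an estimated correlation, fry p = 0.42) and -0.071 for those lower (camera p = 0.00436, and p = 0.521 with an estimated correlation, fry p = 0.603). Over pairs 1 and 2 as recorded, 567 were called in both and 13.4% of them had opposite signs.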

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

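All tests in this part were chosen after the results were seen. Under the sample records, the NFI-EnR change of 2441 probe sets differed between pairs 1 and 2 and pairs 3 and 4 (limma interaction, adjusted p below the threshold), and 98.36% of them had opposite signs in the 2 sets of pairs. Under the authors' column names 2 probe sets differed. Across all probe sets, the mean change of pairs 1 and 2 as recorded had a Pearson correlation of -0.49 and a Spearman correlation of -0.133 with that of pairs 3 and 4. Within each set of pairs the changes went together, with correlations of 0.546 between pairs 1 and 2 and 0.537 between pairs 3 and 4.

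A difference between array batches that shifts both arrays of a pair alike would cancel within the pairs and leave a correlation near 0, which -0.49 argues against. After quantile normalisation of the arrays the correlation was -0.541. RMA, which the authors used, already holds a quantile step, so this value cannot tell whether their normalisation had a part. By this correlation, an exchange of the group names in 1 set of pairs cannot be told apart from a true opposite response of the 2 sets of cultures. Both give a negative correlation, and -0.49 restates the pattern. Which of the 2 sources holds the right names stays open, since both keep the pairs and no gene named here reads the transgene. Gabra6 read 4.129 and 4.065 in the arrays recorded as EnR control 1 and 2, and 4.721 and 5.552 in the undisputed NFI-EnR arrays. The undisputed EnR control arrays read 9.61 and 10.86, and those recorded as NFI-EnR 1 and 2 read 10.63 and 10.89. For this gene a true opposite response would also need control levels that differ between the sets of pairs. Gabra6 is among the genes with the largest changes, so its values do not decide between the sources. No biological explanation was tested, because the labels name no difference between the sets.

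The regrouping of samples bears on the counts. For the NFI arrays 8 of 35 splits into 4 and 4 part all 4 pairs, and only these compare like with like. In 24 others 2 pairs stay together and tell nothing of a change once the pair is a block, and the highest of these gave 26. Under the sample records limma called 0 (2506 at an unadjusted p below 0.05), which all 8 splits reach by definition, and the highest other, 1348, was the split by the authors' names, which points to a structure of the samples. Under the authors' names 1 of the 8, that split itself, gave as many as 1348, and the highest other gave 0. For the probe sets called in both comparisons 1 of the 8 gave as many as 488, and the highest other gave 0. For each of these results 8 splits are too few for a share under 0.05. In the temporal comparison 1 of 10 splits gave as many as 2772, the highest other gave 0, and 10 splits are too few for a share under 0.05.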

How the results depend on the processing

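The authors' naming with its alternatives, the array batch block and the fit without 6 DIV replicate 3 were chosen after the data were seen, and the other alternatives were fixed before the data were examined. The conflict of names limits the NFI comparison and the overlap, the number of arrays limits each comparison, and weak signals near background limit dim probe sets. Of 95 named genes called in the temporal comparison all that were tested kept their direction under each alternative, with 84 of them tested once dim probe sets were left out, and 59 kept the call without replicate 2, the fewest. Of 81 called under the authors' names all that were tested kept their direction except under the sample records, with 78 tested once dim probe sets were left out, and 35 kept the call without the block. The share of higher calls with time was 57.9%, and it ran from 51.2% after quantile normalisation to 68.4% without replicate 3. Scaling moved the median change of all probe sets by between -0.0276 and 0.0119. Further alternatives fixed before, namely the mean of the probe sets of a gene, 1 probe set per gene against all, and camera on the gene lists, were not run, since these need gene names for all probe sets.

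For the temporal count of 2772, the stricter adjusted p below 0.01 gave 995, and leaving out each replicate gave 685 (replicate 2) to 1581 (replicate 3), with 998 without replicate 1. Same-numbered temporal cultures deviated together at -0.0921, 0.206 and -0.184 in the first table and -0.0857, 0.308 and -0.151 in the second, so the numbers do not pair them, and only replicate 2 correlated best with its own number. The replicate block gave 1614. For the NFI count of 0 by limma under the sample records (2506 at an unadjusted p below 0.05), pairs 1 and 2 only gave 2041, pairs 3 and 4 only 1516 and the authors' names 1348, and every other alternative gave 0. Under the authors' names the adjusted p below 0.01 gave 484, no replicate block 279, pairs 1 and 2 only 2041, and leaving out each pair 549 (pair 2) to 1049 (pair 3), with 805 without pair 4. Gene lists past the threshold numbered 3 (without replicate 2) to 6 in the temporal comparison without each replicate, where the 6 without replicate 3 held progenitor and Hedgehog genes (p = 0.044) in place of ion channels (p = 0.0542), and 1 with no replicate block under the authors' names. Pairing changed no other call of a list, except that the temporal replicate block left 5 of 6 lists, without the ion channels.

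In the overlap under the sample records, the median of probe sets higher at 6 DIV was 0.0898 for pairs 1 and 2 only, -0.276 for pairs 3 and 4 only, -0.0213 after quantile normalisation (camera p = 0.026), -0.093 with an estimated correlation (p no longer past the threshold) and -0.2183 to -0.0082 without each pair, no longer past the threshold without pair 4. The median of those lower was 0.129 for pairs 3 and 4 only, -0.252 for pairs 1 and 2 only and -0.1437 to -0.0043 without each pair. It was no longer past the threshold after quantile normalisation (-0.0494, camera p = 0.0522), without dim probe sets (-0.116, camera p = 0.27), with an estimated correlation (-0.0714, camera p = 0.521), without pair 1 or, at -0.016, without pair 2. The correlation across probe sets was -0.2076 to 0.1801 without each pair. Under the authors' names, -0.172 and 0.183 were no longer past the threshold with an estimated correlation, and 108 probe sets were called in both with no replicate block, and 223 (pair 2) to 402 (pair 3) without each pair, with 298 without pair 4. The opposite signs of the pairs under the sample records account for the changes between sets of pairs, and for the others the cause was not tested.

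Grouped by the sample records instead of the authors' names, 63 of the 81 named genes called under the latter reversed, none of them past the threshold then. The log2 changes below 0 were Cxadr -0.97, Cracd -0.75, Rcan2 -0.74, Pcdh17 -0.73, Akap12 -0.70, Neurod6 -0.70, Ebf3 -0.63, Fn1 -0.58, Eomes -0.54, Ctxn1 -0.52, Kcnip4 -0.51, Tubb3 -0.48, Dpysl3 -0.40, Cd24a -0.35, Hsd17b7 -0.34, Dcx -0.30, Barhl1 -0.24, Mcm6 -0.20, Rrm2 -0.19, Frmd4b -0.19, Vim -0.17, Sox4 -0.17, Gja1 -0.15, Ifitm3 -0.11, Top2a -0.10, Mbp -0.094, Gask1b -0.081, S100a10 -0.064, Unc5c -0.049, Cplx2 -0.045, Ccng1 -0.045, Id2 -0.043 and Racgap1 -0.041. Those above 0 were Apoe 1.02, Gfap 0.93, Egr1 0.85, Gabra6 0.78, Unc13c 0.76, Aldoc 0.71, Olig1 0.61, Nptx1 0.60, Cdon 0.51, Wnt7a 0.47, Ppp3ca 0.43, Ccnd1 0.42, Tnc 0.34, Cbln3 0.33, Boc 0.33, Trpm3 0.27, Prune2 0.27, Homer2 0.26, Etv1 0.25, Cdh10 0.23, Ramp1 0.21, Cdh8 0.14, Rora 0.13, Slit3 0.11, Kcnab1 0.097, Syt1 0.059, Slc12a5 0.048, Eno1 0.037, Vsnl1 0.037 and Syn2 0.0099. The exchanged names of 4 arrays account for these reversals by construction.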

Other observations

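All tests in this part were chosen after the results were seen, and so were the genes of this paragraph, from among those named above. Some genes went the same way in both comparisons, by the authors' column names. Of 301 named genes called in both, 8 were higher at 6 DIV and higher with NFI-EnR, among them the protocadherin gene Pcdh17 (log2 change 1.57 with time and 2.89 with NFI-EnR) and the complexin gene Cplx2 (0.89 and 1.14), which binds the vesicle fusion machinery. Another 14 were lower in both, among them the progenitor transcription factor gene Mycn (-1.35 and -1.81), the receptor gene Pdgfra of oligodendrocyte precursors (-1.66 and -1.20) and the cadherin gene Cdh10 (-0.98 and -1.83). Cyclin D1, Ccnd1, went against the other cell cycle genes both times, 1.56 with time and -1.85 with NFI-EnR. The Hedgehog co-receptor genes Boc (1.27 and -1.57) and Cdon (1.65 and -1.19) rose with time, unlike the 7 called members of their list that fell, and with NFI-EnR they were 2 of the 4 that were lower.

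The astrocyte and Bergmann glia genes that were lower in the arrays the authors' table names NFI-EnR raise the hypothesis of fewer glial cells in those cultures. It cannot be told apart from a change within the cells. Of the 16 named members 2 were higher past the threshold, Gja1 (1.75) and Vim (1.36), and 8 of the 11 that were lower lay over 3 standard errors from their median change of -2.18, but other cells may express some members, higher or lower, and low values lie near the floor of the arrays. Apoe stood at 11.86 log2 units in the EnR and 8.52 in the NFI-EnR arrays and Clu at 8.65 and 5.99, all 16 members come from probe sets the authors chose on these samples, and Aldoc is on the Purkinje list too. A direct effect of NFI-EnR on glial genes stays open and was not tested.

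The opposite signs of the 2 comparisons raise the hypothesis that NFI-EnR delays the whole programme of maturation by a common share. Over 120 probe sets at least 4-fold higher at 6 DIV, with an EnR mean of at least 7, the common share of the change with time was -0.439. A uniform delay would leave few probe sets far above it, and 39.2% lay over 3 standard errors above, with 15% at a change of 0 or more, which argues against a delay of all these probe sets alike. A delay of all or part of the programme stays open, with 20.8% over 3 standard errors below the common share and 49.2% lower past the threshold. These values use the authors' column names, and the open question of the names applies to all of them.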
